A study of Mus musculus with 7 samples.

How the data were processed

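The samples were mouse cardiac fibroblasts, the collagen-producing cells of the heart's connective tissue. Per the labels' protocols, they came from hearts of C57BL/6 mice aged 12 weeks, were used at passage 2, starved of serum overnight and then cultured with or without recombinant mouse thrombospondin-4 (TSP-4, a secreted matrix glycoprotein) at 10 ng/ml. The labels call the reagent a recombinant protein, but the catalogue code they give has the form of an antibody code, so what was added could not be checked here. Polyadenylated RNA was sequenced. There were 3 libraries with TSP-4 (letters A, B and D) and 4 without (letters A to D), and the labels gave each library's group and letter. A TSP-4 library of letter C was not analysed here. No label says whether the libraries came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

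The authors deposited a table of raw read counts per gene and a table of FPKM values for the same 54532 genes. Per the submitters' processing notes, CASAVA, TopHat2 2.0, Cufflinks 2.1.1 and HTSeq 0.6.1 were used and the builds were mm10 and GRCm38.p6; the role of each tool and the strand setting of the counting are not given in the sources used here. The deposited FPKM values equalled counts divided by gene length and library total, times a constant per library between 0.980 and 1.01, with no gene departing from it beyond rounding. They therefore held no information beyond the counts. Of the deposited gene identifiers, 54495 were found in the GENCODE M21 annotation of GRCm38, and 53585 of those had the same start and end. Coordinates are those of the deposited tables.

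Counts were tested in R 4.3.3 with the quasi-likelihood F-test of edgeR 4.0.16 (robust, TMM scaling), with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. After edgeR's expression filter, 15207 genes were tested. The main design compared all 7 libraries without a block, with 5 residual degrees of freedom. The letter as an additive block was a second design, and the rule for accepting the letters as pairs was set before the data were examined, as were the test, the gene lists and the other settings compared below. Deviations of same-letter libraries from their group means correlated across genes at 0.467 for letter A, 0.587 for B and 0.355 for D. Correlations between different letters were 0.00453 or lower, but this adds little, since deviations from a group mean cancel within the group. The same-letter values all lay above the bound of 0.1. The letters were therefore taken as pairs, from the data and not from a statement in the labels. The paired fit had 2 residual degrees of freedom, and control C informed no within-pair difference. Its biological coefficient of variation was 4.78%, against 14.7% without the block.

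Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with the correlation estimated from the data and with fry beside it; of 39 lists, 35 had the 5 expressed members that a test needed. DESeq2 1.42.0, limma-voom, other scalings and filters, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), and fits without each library were run beside it. All repeats of these inside the paired fit were added after the data were seen, as were corrections for GC content and gene length and thinning of the counts to equal totals. Library measures were compared with two-sided exact permutation tests over 35 splits, whose smallest possible p is 0.0286.

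The genes named were 10 anchors fixed in advance, up to 12 higher and 12 lower genes past the threshold whose TSP-4 libraries all lay on one side of all controls, the genes of smallest p up to 10, and up to 4 members of smallest p in each list. Predicted genes and pseudogenes were left out of the rule, and it was applied to both fits. Some genes that it takes are not reported here. CPM values were scaled by the TMM-adjusted total of the tested genes, except those of Thbs4 and of summed copies, which were scaled by library total. Log2 fold changes are TSP-4 over control with their standard error (SE). The procedure was tested on simulated counts of the 7 libraries with 200 of 15091 genes changed. For a 1.5-fold change 26% were recovered without the block and 66% with it, and for a 1.2-fold change 0% and 40%. The paired fit made 4 false calls beside 118 true ones, and the unblocked fit 0 beside 39. The simulation gave libraries of a letter a shared mean and all genes the common dispersion of the paired fit. The paired model therefore held by construction, and these figures do not give the error rate of the real calls.

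Library totals ran from 18010519 to 23096971 counts. No 2 libraries of a group agreed within sampling noise, since the chi-square per degree of freedom between them was at least 8.25.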

Results

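Gene expression was measured by RNA sequencing in cultured mouse cardiac fibroblasts kept without TSP-4 (n = 4) or with it (n = 3). The total counts were 19083470, 22473866, 19633000 and 23096971 in controls A, B, C and D, and 20866157, 19983329 and 18010519 in TSP-4 libraries A, B and D. The comparison asks how the transcriptome of these cells differs after exposure to TSP-4.

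Taken as 2 independent groups, the libraries gave no gene that passed the test for TSP-4 against control. Compared within the 3 letter pairs, cells with TSP-4 had higher mRNA of the cholesterol synthesis enzymes Mvk and Lss. They also had lower mRNA of the ETS transcription factors Etv5 and Etv4, of the proliferation marker Mki67 and of the lipase inhibitor Angptl4. Most changes were small, and Mvk, Etv4 and Mki67 were not called when pair D was left out. The myofibroblast gene Acta2 and the collagens Col1a1 and Col3a1 passed neither test.

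Without the block, 0 genes were higher and 0 lower by edgeR's quasi-likelihood test, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 311 genes, where chance gives 760.35 for independent libraries. Differences between letters widen the unblocked spread, so the lower number is no evidence against a change. DESeq2 called 0 higher and 1 lower, Tnfsf18, and limma-voom called 0. With the letter as a block, edgeR called 147 genes, 58 higher and 89 lower, with 1659 at an unadjusted p under 0.05. Of the 147 called, 125 changed by less than 1.5-fold. In all 3 pairs 145 went the same way, but the paired fit selects on that property. The paired count rests heavily on pair D: without it 23 genes were called, of which 14 were among the 147, and without pair B 87 were called, 60 of them shared. Of the 147, 13 passed with each pair left out in turn, 9 of them also by paired DESeq2, and 3 predicted genes among the 13 lost the call when summed with near-identical copies. The 13 included Angptl4, Etv5, Tnfsf18, Scd2, Adamts9, Nedd4l, Adamts1 and Lss, and most other genes named as changed did not pass without pair D. Limma on the FPKM values called 0 genes in the same paired design, with a smallest adjusted p of 0.0915 for a pseudocount of 1.

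**Figure D1:**
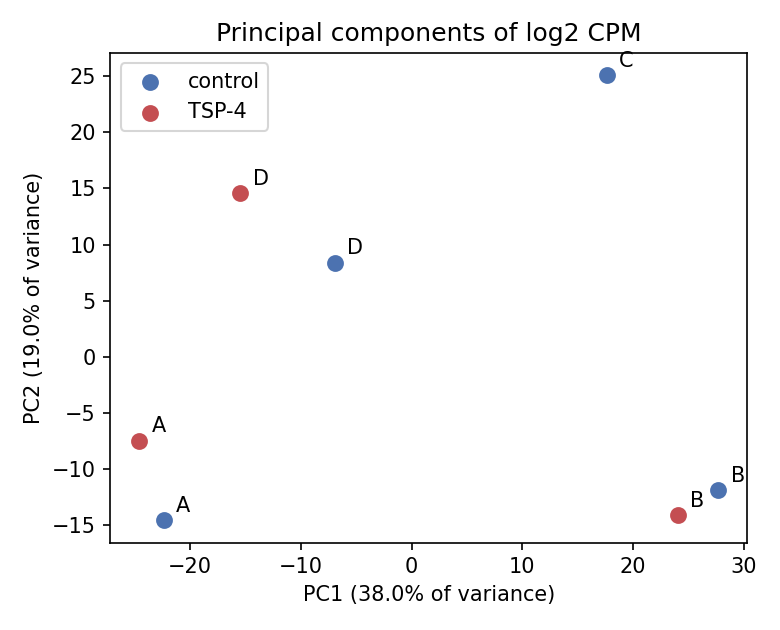
Principal components 1 and 2 of the log2 CPM values of the 7 libraries, with 38.0% and 19.0% of the variance on the x and y axes; colours mark control and TSP-4 and letters mark the replicate. Along the first component libraries of letter B lie at 27.7 and 24.0 and those of letter A at -22.4 and -24.6, so that letters A and B differ more than treatments within them. Control D and TSP-4 D lie further apart, at -6.91 and -15.4.

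The cholesterol synthesis and uptake list passed camera at the preset correlation within the pairs (adjusted p = 7.05e-36) and without the block (1.38e-17). With an estimated correlation the adjusted p was 0.596 in the paired fit and 0.835 without the block, and fry gave 0.222 and 0.964. Of its 25 measured members 12 rose, 0 fell and 13 did not pass (21 rose when adjusted over the list alone), with a median log2 fold change of 0.21. The medians were 0.21, 0.21 and 0.17 in pairs A, B and D. Mvk, mevalonate kinase, rose from 78.8 ± 11.3 CPM (SD, n = 4) to 101 ± 14.5 (SD, n = 3), a paired log2 fold change of 0.33 (SE 0.0485, adjusted p = 0.00217 by edgeR). Lss, lanosterol synthase, rose by 0.33 (SE 0.0493), the sterol dehydrogenase Nsdhl by 0.33 (SE 0.0520) and mevalonate diphosphate decarboxylase Mvd by 0.29 (SE 0.0534).

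Among fatty acid and lipid handling genes 2 of 34 rose, 1 fell and 31 did not pass (9 rose and 2 fell when adjusted over the list alone). The stearoyl-CoA desaturases Scd2 and Scd1 rose by 0.33 (SE 0.0402) and 0.27 (SE 0.0445) on the log2 scale. Angptl4, a secreted inhibitor of lipoprotein lipase, fell by 0.61 (SE 0.0645, adjusted p = 0.000207 by edgeR), from 64.2 ± 22.6 CPM (SD, n = 4) to 44.4 ± 13.6 (SD, n = 3). Acly, ATP-citrate lyase, had a paired log2 fold change of 0.15 and did not pass. The median of the list was 0.12 and camera's adjusted p 0.000437. With an estimated correlation the adjusted p was 0.616, and without pair A it was 0.118 at the preset correlation. Acss2, which makes acetyl-CoA from acetate and is in neither list, was higher in every TSP-4 library than in every control and rose by 0.49 (SE 0.0806).

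Immediate early genes, which respond to growth factor signalling within minutes to hours, had a negative list median in 2 of the 3 pairs, and camera's adjusted p was 5.39e-13 in the paired fit and 6.36e-12 without the block. The adjusted p was 0.616 and 0.835 with an estimated correlation. Of 36 members 7 fell, 0 rose and 29 did not pass (15 fell and 1 rose when adjusted over the list alone). The median was -0.34 in pair B and -0.33 in pair D but 0.01 in pair A. The ETS factors Etv5 and Etv4 fell by 0.59 (SE 0.0692) and 0.83 (SE 0.128), the AP-1 subunit Fosl1 by 1.31 (SE 0.200) and the Ras-ERK inhibitor Spred1 by 0.34 (SE 0.0498). All 4 of these were lower in every pair, Fosl1 by 0.32, 1.78 and 1.24 in A, B and D. Macrophage markers, by their list median, were 0.15 higher in pair A and 0.13 and 0.05 lower in pairs B and D on the log2 scale.

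**Figure D2:**
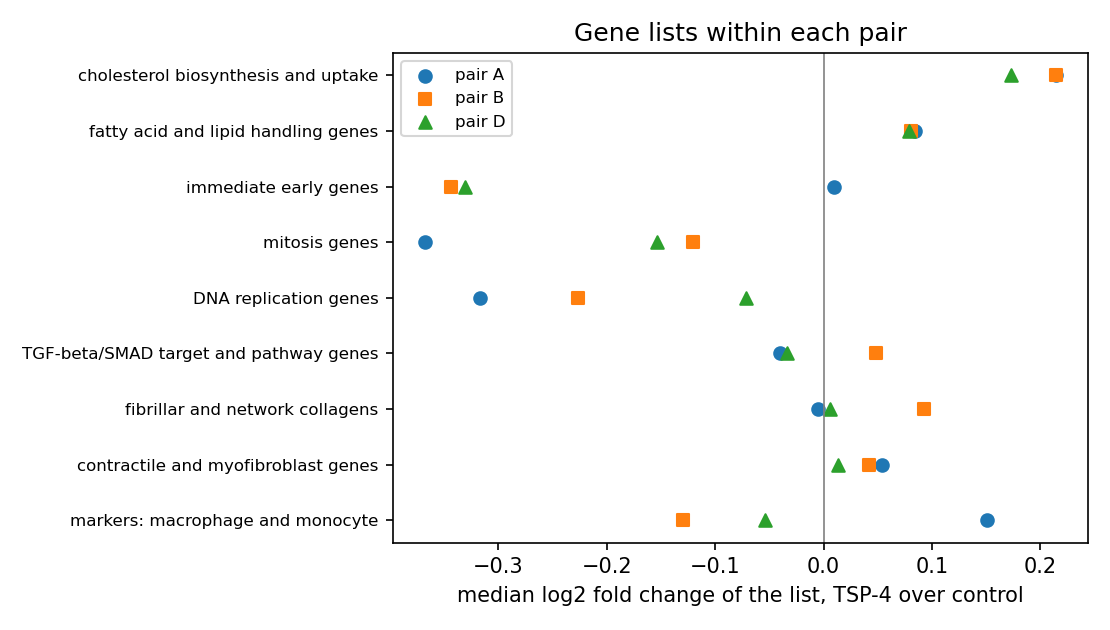
Median log2 fold change of TSP-4 over control (x axis) for 9 gene lists (y axis) within pairs A, B and D, 1 symbol per pair; where symbols overlap they have nearly the same value. The cholesterol list lies between 0.17 and 0.21 in the 3 pairs, and the immediate early list at 0.01, -0.34 and -0.33 in A, B and D.

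The mitosis and DNA replication lists had negative medians in all 3 pairs and passed camera at the preset correlation in the paired fit (adjusted p = 3.49e-22 and 5.39e-13). With an estimated correlation the adjusted p was 0.616 for both, and fry gave 0.283 for both. In the mitosis list 5 of 40 members fell, 0 rose and 35 did not pass (17 fell when adjusted over the list alone), and in the DNA replication list 2 of 36 fell, 0 rose and 34 did not pass (10 when adjusted over the list alone). Mki67 fell by 0.41 (SE 0.0633, adjusted p = 0.00291 by edgeR), the mitotic transcription factor Foxm1 by 0.31 (SE 0.0682), the kinetochore gene Knl1 by 0.48 (SE 0.101) and the cytokinesis gene Anln by 0.23 (SE 0.0529). Uhrf1 and Rrm2, which serve DNA methylation upkeep and nucleotide supply, fell by 0.39 (SE 0.0815) and 0.32 (SE 0.0753). The medians in pairs A, B and D were -0.37, -0.12 and -0.15 for mitosis and -0.32, -0.23 and -0.07 for replication. Without the block the mitosis list did not pass (adjusted p = 0.302) and the replication list did (adjusted p = 0.000569, and 0.879 with an estimated correlation). The unblocked mitosis list passed in the opposite direction without control B (median 0.28, adjusted p = 7.74e-05) and without TSP-4 A (median 0.23, adjusted p = 7.35e-05). The unblocked replication list no longer passed without either of these libraries (adjusted p = 0.720 and 0.846). Each of these fits left a library without its partner of the same letter, so differences between letters entered the comparison. Within pairs A, B and D, 39, 33 and 33 of the 40 mitosis members were lower with TSP-4.

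TGF-beta and SMAD pathway genes did not change as a list (camera adjusted p = 0.309 with the block and 0.291 without). Of 28 members 0 rose, 2 fell and 26 did not pass (1 rose and 2 fell when adjusted over the list alone). Among the members that fell was the signal transducer Smad3, which fell by 0.31 (SE 0.0627, adjusted p = 0.0227 by edgeR). Ctgf had a paired log2 fold change of -0.12 (SE 0.0411) and Tgfb1 one of -0.05 (SE 0.0489), and neither passed.

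Of the collagens 1 of 21 members rose, 1 fell and 19 did not pass (4 rose and 1 fell when adjusted over the list alone). The list did not pass in the paired edgeR fit (camera adjusted p = 0.210) and passed in the paired DESeq2 fit (median 0.04, adjusted p = 0.0449). In the paired edgeR fit the adjusted p was 0.854 with an estimated correlation, and fry gave 0.645. The fibrillar Col11a1 rose by 0.24 (SE 0.0482) and Col15a1 fell by 0.29 (SE 0.0682). Col3a1 had a paired log2 fold change of 0.15 (SE 0.0377, adjusted p = 0.0731 by edgeR), Col1a1 0.04 (SE 0.0380), Fn1 0.07 (SE 0.0397) and Postn 0.10 (SE 0.0461), none of which passed. Contractile genes gave 2 of 30 higher and 1 lower, with camera's adjusted p at 0.112, and at 0.0464 on unfiltered FPKM. With an estimated correlation it was 0.616 in the paired edgeR fit, and fry gave 0.392. Enteric smooth muscle actin Actg2, at a mean of 2.02 CPM in controls, rose by 1.07 (SE 0.221), and Tagln2 fell by 0.31 (SE 0.0474). Acta2, the usual marker of myofibroblasts, had a value of 0.08 (SE 0.0389) and did not pass. Synpo2 rose by 0.25 with the block and had a value of -0.05 without it.

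The non-collagen matrix list (median 0.04, adjusted p = 0.0415) and the collagen processing list (median 0.05, adjusted p = 0.0285) passed camera in the paired fit although 0 of their 35 and 25 members passed alone. With an estimated correlation the adjusted p was 0.616 for each, and neither list passed without pair B (adjusted p = 0.276 and 0.226), with offsets for GC content (0.0832 and 0.159) or without the block (0.382 and 0.291). In the list of matrix proteases and inhibitors 1 of 33 rose and 3 fell. Adamts1 rose by 0.32 (SE 0.0454), and Adamts9, Adam19 and Adam12 fell by 0.46 (SE 0.0585), 0.29 (SE 0.0612) and 0.36 (SE 0.0813). Adamts1 was higher in unpaired control C (483 CPM) than in TSP-4 A, B and D (448, 449 and 475). Controls A, B and D had 386, 329 and 388, and the unblocked log2 fold change was 0.21.

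**Figure D3:**
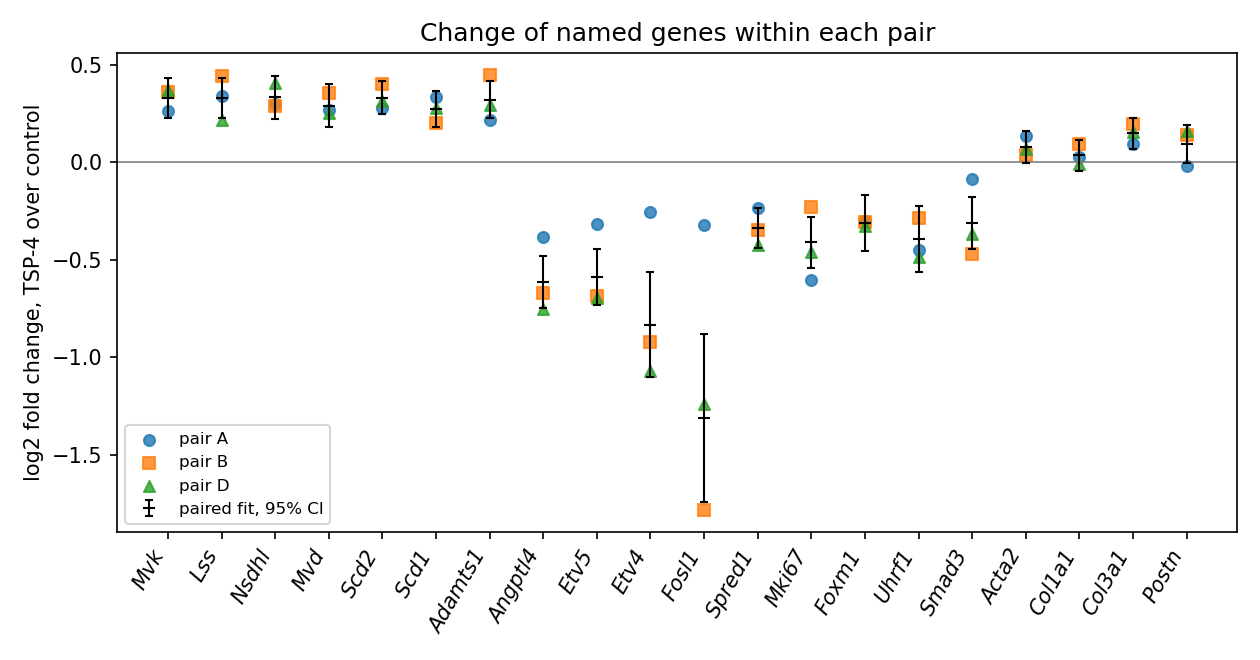
Log2 fold change of TSP-4 over control (y axis) of 20 named genes (x axis) within pairs A, B and D, with the paired edgeR estimate and its 95% confidence interval in black. Mvk, Lss, Nsdhl and Mvd lie above 0 in all 3 pairs, and Etv5, Etv4 and Fosl1 lie below 0 in all 3, least so in pair A.

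Several genes outside these lists or shared with them were lower in every TSP-4 library than in every control and fell in the paired fit. Tnfsf18, the ligand of the receptor GITR, fell by 1.41 (SE 0.169), from 7.59 ± 2.17 CPM (SD, n = 4) to 2.97 ± 0.317 (SD, n = 3). Its unblocked log2 fold change was -1.35 (SE 0.241, adjusted p = 0.999 by edgeR), and DESeq2 called it without the block but not with it. The ubiquitin ligase gene Nedd4l fell by 0.43 (SE 0.0548), the caspase-8 inhibitor Cflar by 0.26 (SE 0.0447), Eps8 by 0.33 (SE 0.0594), Hmga2 by 0.78 (SE 0.142) and the semaphorin Sema7a by 0.74 (SE 0.159). Arc fell by 1.95 (SE 0.365), at 1.55 CPM or less in either group's mean. Rasa1 fell by 0.26, Cyth3 fell by 0.22 and Socs5 fell by 0.21. Srp54b fell by 1.08 (SE 0.135), and by 0.44 (SE 0.0597) when its counts were summed with those of its near-identical paralogs. Its separation was marginal, at 10.85 CPM in control C and 10.81 in TSP-4 B. The summed counts were not separated, with 36.3 CPM in control C and 39.1 in TSP-4 A. In all 571 genes, 3.75% of those tested, had TSP-4 libraries entirely on one side of the controls, and chance gives 5.71% for independent libraries. Same-letter libraries were correlated, so that figure does not hold here, and the lower share is no evidence against a change.

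In the inflammatory list 0 of 36 rose and 3 fell, and the list lay near the threshold. Camera's adjusted p was 0.0541 in the paired edgeR fit, 0.0156 with DESeq2, 0.0227 with limma-voom and 0.000238 without pair A. With an estimated correlation the adjusted p was 0.616 in the paired fit, and fry gave 0.449. Without the block its median was -0.05 (adjusted p = 0.291), and -0.35 without TSP-4 B (adjusted p = 0.000582) and -0.14 without control A (adjusted p = 0.0239). Within pairs A, B and D the list's median was 0.02, -0.06 and -0.06. The macrophage marker medians had the same signs (0.15, -0.13 and -0.05), and a contribution of macrophage content was not tested. Ccl7 fell by 0.42 (SE 0.0808), Cxcl5 by 0.32 (SE 0.0682) and the adhesion molecule Vcam1 by 0.17 (SE 0.0397). Among growth factors and ligands Hbegf fell by 0.44 (SE 0.0875). Thrombomodulin, Thbd, rose by 0.21 (SE 0.0454), the vasodilator peptide gene Adm fell by 0.22 (SE 0.0489), and in the YAP and TAZ target list Gadd45b rose by 0.25 (SE 0.0556) and Myof fell by 0.22 (SE 0.0444). The YAP and TAZ list had a median of 0.01 but a mean of -0.01, and camera, which ranked it as lower, gave an adjusted p of 0.967. The ER chaperone and folding list had 0 of 30 members past the threshold and a camera adjusted p of 0.201.

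The genes of smallest unblocked p that the paired fit did not call are given as values. Tlr4 had an unblocked log2 fold change of -0.24 (SE 0.0621), Noc3l of -0.26 (SE 0.0702), Alg9 of 0.27 (SE 0.0593) and Yars2 of -0.33 (SE 0.0854). Atp6v1b1, Ddx4 and Trpc5os, all under 1 CPM on average, had values of -1.92, -1.76 and -1.30; Trpc5os is annotated as an opposite-strand gene, and its counts are uncertain because the strand setting is not given. Sumo2 stood at 32.4 and 41.4 CPM in TSP-4 libraries A and B but at 7.72 in D, and between 5.93 and 7.53 in the controls. Its counts are uncertain, since summed with 5 near-identical copies the paired log2 fold change was 0.25 (SE 0.102, adjusted p = 0.414 by edgeR).

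Thbs4 itself, the gene encoding TSP-4 (chromosome 13, 92751590 to 92794818, GRCm38), had 1, 1, 4 and 8 counts in controls A, B, C and D and 2, 0 and 3 counts in TSP-4 libraries A, B and D. It was below the filter and was not tested. A count of 0 allows up to 0.150 CPM in TSP-4 library B, for counting error only.

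Angptl4 (ENSMUSG00000002289) lies on chromosome 17 from 33773750 to 33781575, Etv5 (ENSMUSG00000013089) on chromosome 16 from 22381309 to 22439719, Mvk (ENSMUSG00000041939) on chromosome 5 from 114444269 to 114460591, Scd2 (ENSMUSG00000025203) on chromosome 19 from 44293676 to 44306864 and Tnfsf18 (ENSMUSG00000066755) on chromosome 1 from 161494655 to 161505290, in GRCm38.

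Markers of macrophages, immune cells that can persist in primary fibroblast cultures, varied more between letters than with TSP-4. The mean log2 CPM of the list was 4.32 for letter A, 4.95 for D, 5.44 for B and 6.08 for control C, a 3.38-fold range. Lyz2, the most abundant of them, had 1692 ± 818 CPM in controls (SD, n = 4) and 1337 ± 411 with TSP-4 (SD, n = 3). The list was lower with TSP-4 in the unblocked camera test (median -0.39, adjusted p = 0.000569), but with an estimated correlation the adjusted p was 0.879, and in the paired fit it was 0.513 with a median of -0.02. The unblocked call was lost without control C (adjusted p = 0.853) or TSP-4 A (0.475), and the paired list passed without pair A (median -0.07, adjusted p = 0.00637). Of 15 library measures, the cardiomyocyte marker list had the smallest exact p, 0.0286, the smallest the design allows, with an adjusted p of 0.429. That list lay near the floor, with 4 of 19 members past the expression filter. Its mean log2 CPM was -1.96 in controls and -1.76 with TSP-4.

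**Figure D4:**
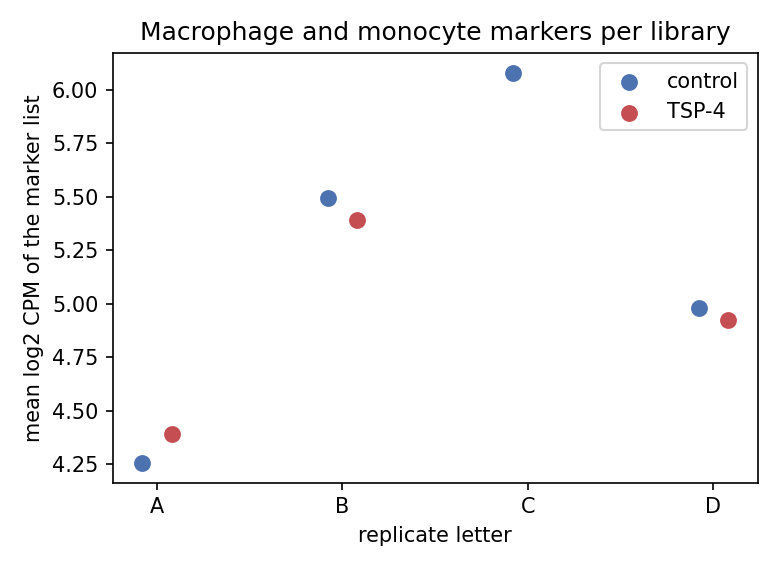
Mean log2 CPM of the macrophage and monocyte marker list (y axis, not starting at 0) for each library by replicate letter (x axis), control and TSP-4 in different colours. Libraries of a pair lie within 0.14 of each other, while the letter means run from 4.32 to 6.08.

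**Figure D5:**
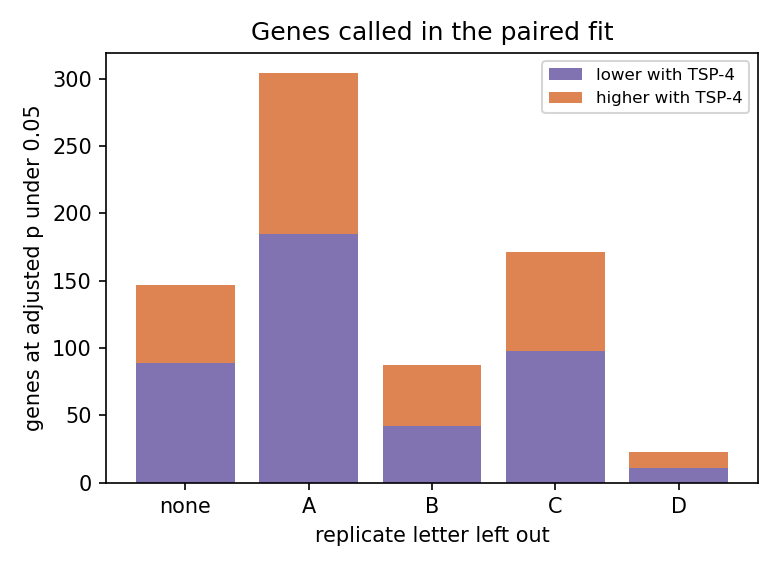
Genes at adjusted p under 0.05 in the paired edgeR fit (y axis, lower and higher with TSP-4 stacked) with all libraries and with each replicate letter left out (x axis). The total is 147 with all libraries, 304 without A, 87 without B, 171 without C and 23 without D.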

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

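In 8 of 182 sets of 4 control values, 1 library lay far from the other 3 by Dixon's criterion, where chance gives about 1 in 20, or 9.1. No explanation was tested for these values. In control B the collagen gene Col11a1 was at 161 CPM (median of the others 188), the matrix gene Cthrc1 at 97.4 (145), the stress transcription factor gene Atf4 at 148 (171) and the cardiac troponin gene Tnni3 at 0.439 (0.566). The 10 most abundant genes took 6.47% of counts in control B, against a median of 7.29% in the other controls. In control C Postn, a matricellular gene of activated fibroblasts, was at 275 CPM (168) and the glucocorticoid-induced gene Tsc22d3 at 30.03 (23.5). The adipocyte marker list, of which 1 of 10 members passed the expression filter, had a mean log2 CPM of -2.37 in control C. The median of the others was -2.71.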

How the results depend on the processing

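The repeats of the paired fit below were chosen after the data were seen; the settings without the block were fixed before. Without the block, other settings called 0 genes except DESeq2 (1 lower, Tnfsf18, adjusted p = 0.00354), the fit without TSP-4 D (1 higher, Sumo2, adjusted p = 0.00343; higher calls ranged from 0 to 1 and lower were 0 over the leave-outs) and the block on the letters, with 58 higher and 89 lower. Pairing by letter thus decided whether genes were called; the cause was not tested beyond the lower spread within pairs. In the paired design DESeq2 called 30 higher and 27 lower (54 of these 57 shared), limma-voom 94 higher (145 of 206 shared) and the unfiltered fit 34 higher and 58 lower. Limma on FPKM called 0 higher and 0 lower with either pseudocount or no filter, with smallest adjusted p of 0.0915, 0.302 and 0.768 and 1246, 1220 and 1385 genes at an unadjusted p under 0.05. An adjusted p under 0.01 left 14 higher and 24 lower, and under 0.1 gave 106 higher. Leaving out a letter gave 12 to 119 higher and 11 to 185 lower, the fewest without D. Other scalings, the stricter filter and legacy dispersion gave 150 to 162 calls. The cause was not tested for any of these.

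Synpo2 was 0.25 with the block and -0.0522 without. Postn, not called in either fit, was 0.10 and -0.12. Control C, which informs no within-pair difference, was high for both and so lowered the unblocked values. It had 94.3 CPM of Synpo2, against 44.2, 52.4 and 48.4 in controls A, B and D. For Postn it had 275 CPM, against a median of 168 in the other controls. Many list medians near 0 changed sign over the leave-outs. Those that did so where the list passed with or without the library ran from -0.0554 (without TSP-4 D) to 0.11 for BMP targets, -0.24 to 0.0286 (without control A) for interferon-stimulated genes, -0.38 to 0.0117 (without TSP-4 A) for DNA replication and -0.53 to 0.28 (without control B) for mitosis, which was also 0.23 without TSP-4 A. With the block, ribosomal protein genes ran from -0.0291 (without D) to 0.0724. The cause was not tested. The inflammatory list, which did not pass in the paired fit, passed there with DESeq2, limma-voom, the stricter filter, legacy dispersion, length offsets and thinning. The block changed the calls of the mitosis, matrix, collagen processing, integrated stress response, FoxO, interferon, macrophage and endothelial lists and of no other list.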

Other observations

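Tests of depth, near-identical copies, the ERK signature, macrophage markers between libraries, and macrophage content against the cholesterol and mitosis lists were chosen only after the results were seen. In the paired fit the integrated stress response list (median 0.06, adjusted p = 0.0456) and the FoxO target list (median 0.04, adjusted p = 0.0415) passed camera while 0 of their 25 and 26 members passed alone; with an estimated correlation the adjusted p was 0.616 for both, and without the block 0.786 and 0.382. With offsets for GC content the integrated stress response list had an adjusted p of 0.176, and without pair D neither passed (0.133). Interferon-stimulated genes passed without the block (median -0.09, adjusted p = 0.0158) and not with it (0.0610), and endothelial markers likewise (median -0.14, adjusted p = 0.0158, and 0.0521 with the block). With an estimated correlation the unblocked adjusted p was 0.879 for both. Both lists lay near the threshold in the paired fit: limma-voom gave adjusted p of 0.0164 and 0.0495, and without pair B they were 4.84e-05 and 0.0202. The interferon list had medians of -0.26, 0.06 and 0.08 in pairs A, B and D, so it was lower in pair A only. Endothelial markers had medians of -0.09, -0.05 and -0.11. Among integrins and thrombospondin receptors 0 of 29 members passed, 2 rose and 4 fell when adjusted over the list alone, and camera's adjusted p was 0.833. Cyclin D1, Ccnd1, fell by 0.35 (SE 0.0420) and the microfibril-associated gene Adamtsl2 rose by 0.38 (adjusted p = 0.00598 by edgeR) in the paired fit, both named after their values were seen.

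Genes were called within pairs but not between the groups. Without the block the real count was 0, which 35 of 35 splits reach by construction, so the splits say nothing about chance. A split of control B, control C and TSP-4 B from the rest called 1346, so these libraries stood apart. Other splits that part no pair called few: 3 for control C, control D and TSP-4 D, and 0 for control A, control C and TSP-4 A. With the block, 1 of the 4 arrangements within pairs called as many as the real 147 and the highest other called 1; 4 arrangements are too few for a share under 0.05. Of the 147 calls, 135 were kept with offsets for GC content and 139 with offsets for gene length, which argues against these as the whole cause. After thinning to equal totals 146 were kept. That decides little about depth, since totals ran only from 18010519 to 23096971 and the fit already scales by total. An earlier depth test, on the share of calls with the same direction in all pairs (98.6%), was set aside because calls are selected on that property.

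The immediate early list had negative medians in pairs B and D. A difference in macrophage content may contribute, but only the signs go with it. In pair A, where the macrophage markers were higher, the list's median was 0.00986, and in the other pairs, where they were lower, it was negative. Signs over 3 pairs cannot decide this, and the sizes did not follow. The list's median was -0.34 and -0.33 in pairs B and D, where the macrophage median was -0.13 and -0.05. The cholesterol list had at least 23 of 25 members higher in each pair, and the mitosis list at least 33 of 40 lower, which argues against macrophage content for those. Lower ERK pathway output is a candidate explanation for the immediate early list. In a MAPK activity signature 8 of 10 genes were lower in all 3 pairs, against 16.1% of all genes, and 4 of the 10 were called. Most of the signature is no separate evidence, since Phlda1, Spry2, Spry4, Dusp4, Dusp6, Etv4 and Etv5 are in the list itself. Outside the list, Ccnd1 and Epha2 were lower in all 3 pairs and Epha4 was higher in all 3, so the signature cannot decide the question. These explanations do not exclude each other.

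Macrophage markers differed between letters. The largest difference within a pair was 0.14 in mean log2 CPM, with opposite signs in different pairs, which argues against TSP-4 as the cause. The smallest difference between letters was 0.49, consistent with a difference between cultures of origin, although the labels do not say that a letter is a culture. The change with TSP-4 in each pair correlated across 11289 genes with the difference between the other cultures at 0.120, 0.234 and 0.266 (A, B and D). The sign of these values decides nothing, since the difference was oriented by the cholesterol list, already known to be higher in each pair, and genes are not independent replicates.

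Of 23 called genes with a near-identical copy, 17 were still called when summed with the copies. Rpl17 had a summed log2 fold change of 0.0157 (SE 0.0439), while its own fell by 1.17 (named after its values were seen). Its copy Rpl17-ps10 had 68.4, 84.8 and 99.4 CPM by library total in controls A, B and D, and 187, 148 and 188 in TSP-4 A, B and D. Control C, without TSP-4, had 56.7 CPM of Rpl17 and 167 of the copy. A fall of Rpl17 alone would have lowered the sum, so these values argue against it. Of the other 5 genes that lost the call, the sums of 3 lay within 2 SE of 0. Of these, Gm44126 and Gm14434 had 2.50 and 0.725 CPM in controls, a small part of sums of at least 49.97 and 25.8 CPM, so that a change of their own would hardly move the sum. For the 5 as a set, split reads cannot be told apart from a change.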
